A study of Sus scrofa with 23 samples.

How the data were processed

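Liver RNA from 23 pigs was measured by RNA sequencing. Per the labels' protocols, total RNA was extracted with Qiagen miRNAeasy kits, and library preparation followed a standard Illumina method. The deposited table held a raw read count per gene and library. Per the submitters' processing notes, reads were aligned with HISAT and DESeq2 was used. The genome build, the annotation, the read counter and the strand setting are not given in the sources used here, so no coordinates are given, and counts of overlapping genes, antisense genes and near-identical copies (serum amyloid A, globin, cytochrome P450 and MHC genes among them) are uncertain. The values were whole numbers with different totals per library, so they had not been divided by size factors.

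Each column was assigned to a pig by its name, which matched the sample titles. The groups were uninfected on the control diet, uninfected on PAC, infected on the control diet and infected on PAC, with 6, 6, 6 and 5 pigs. The diet of the uninfected PAC pigs was taken from their titles, and the labels describe separate animals. Of 30648 genes in the table, 30335 carried an NCBI gene number that matched the RefSeq gene table, from which names were taken. 13 of these names, all septins, stood as dates in the deposited table. Another 24 had an RNA number and no name, took at most 0.0223% of counts and were kept as genes too. The other 289 had no known name, took 0.500% to 1.19% of counts and stayed in the library sizes and tests as genes. A few symbols stand for more than 1 gene number, and each was tested as its own gene. No libraries agreed within sampling noise: over 55 pairs within groups, the chi-square per gene lay between 27.3 and 256.

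Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with robust dispersion, TMM library factors, a mean for each of the 4 groups and all 23 libraries in the fit. The filter of edgeR by group left 15955 genes. There were 7 comparisons: infection on each diet, PAC in uninfected and in infected pigs, infection averaged over the diets, PAC averaged over infection, and the interaction of both. Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05. CPM used the TMM-scaled library sizes, and log2 CPM values a prior count of 2. Fold changes came from the edgeR fit with its default prior count. Fold changes of genes with few counts depend on that default.

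The groups, tests, alternatives, 44 gene lists and the rule for naming genes were chosen before the data were examined. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 on voom values, where at least 5 members were tested, which held for 42 lists; the eosinophil list had 4 tested members and the sex chromosome list 1. camera was repeated with an estimated correlation, under which 0 lists passed in any comparison, and fry was run for shared direction and for change in either direction. Over the 7 comparisons camera called 17 lists, 11 up and 6 down. Fry's test for shared direction called 12, of which 3 were also called by camera. It called 0 for infection on the control diet, for the interaction and for each PAC comparison. The rule named, in each comparison, the 8 largest changes up and down among genes past the threshold with a symbol, a mean of at least 1 CPM and at least 80% of libraries on the changed side of the other group's median; up to 4 members of each list past its threshold; and a fixed panel of 32 genes. Where fewer than 10 genes passed all were named, and where 0 passed the 5 with the smallest p. A few genes that the rule or the lists gave are not reported here. Other genes named as members of lists that did not pass, among them clock and acute-phase genes, were chosen after their values were seen.

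The fit was tested on simulated counts with 200 genes changed. For infection on the control diet it recovered 45.1% of 1.5-fold and 75.0% of 2-fold changes, on the PAC diet 37.2% and 72.4%, for PAC in uninfected pigs 41.5% and 68.5%, and for PAC in infected pigs 37.7% and 75.8%. False calls made up 2.41% to 8.70% of calls. All of 20 simulated lists of 20 genes shifted by 0.3 were found at p under 0.05, and 1 of the unshifted lists. Genes were drawn independently there, so the simulation does not show how often lists of correlated genes are called falsely. In random splits of the real libraries camera called up to 21 lists.

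Alternatives chosen in advance were other library factors (RLE), no filter, a filter of at least 1 CPM in at least 11 libraries, DESeq2 1.42.0, limma voom with library quality weights, only the groups compared, the replicate number as a block, an adjusted p under 0.01, and leaving out each library. EIF1AY as a covariate, the fit without both libraries with high acute-phase transcripts and the comparison of infection on PAC with PAC in uninfected pigs were added after seeing the data.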

Results

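RNA was sequenced from the livers of 23 Danish Landrace × Yorkshire pigs to ask how infection with the roundworm Ascaris suum, whose larvae pass through the liver on their way to the lungs, changed gene expression there, and whether a diet with grape seed proanthocyanidins (PAC, plant polyphenols) altered that response. Pigs aged 10 weeks were given 5000 eggs or none and were killed 14 days later. The diets, control or with 1% PAC, were fed for 28 days, of which 14 came before infection. The groups were uninfected on the control diet (n = 6), uninfected on the PAC diet (n = 6), infected on the control diet (n = 6) and infected on the PAC diet (n = 5). The table held whole-number counts for 30648 genes. Totals ran from 16299240 counts (infected, control diet, replicate 4) to 29535440 (uninfected, PAC diet, replicate 2), with a median of 23020225, and 15955 genes passed the count filter and were tested. Expression is given as CPM, counts scaled to a common library size (mean ± SD over pigs), and changes as log2 fold changes with their standard error (SE).

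The source label and the title name liver, while the design text speaks of lungs, so tissue identity was read from the counts. Albumin (ALB), the main secreted protein of hepatocytes, stood between 25820 and 113474 CPM, with a median of 85893 CPM over the 23 libraries. SFTPC, which encodes a surfactant protein of lung alveolar cells, stood between 0.0803 and 1.15 CPM. The 20 lung epithelium genes on the fixed list took at most 0.0215% of any library's counts, and the hepatocyte genes took 17.3% to 25.9%. By these markers the libraries held liver RNA. A pair of pigs carried high acute-phase transcripts. Infected control-diet replicate 4 had 1924 CPM of SAA3 (serum amyloid A) and 11441 CPM of ITIH4, and uninfected PAC-diet replicate 5 had 529 and 6122 CPM, while SAA3 in the other 21 libraries lay between 10.8 and 59.0 CPM. ALB was lowest in the same pigs, at 25820 and 44007 CPM. EIF1AY, a Y-linked gene, was counted in 12 libraries and had no count in 11. It was split 3 and 3 in each group of 6 and 3 and 2 in the infected pigs on PAC, so it was not tied to infection or diet. The first principal component held 16.7% of the variance, and 11 of its 15 leading genes were Y-linked.

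**Figure D1:**
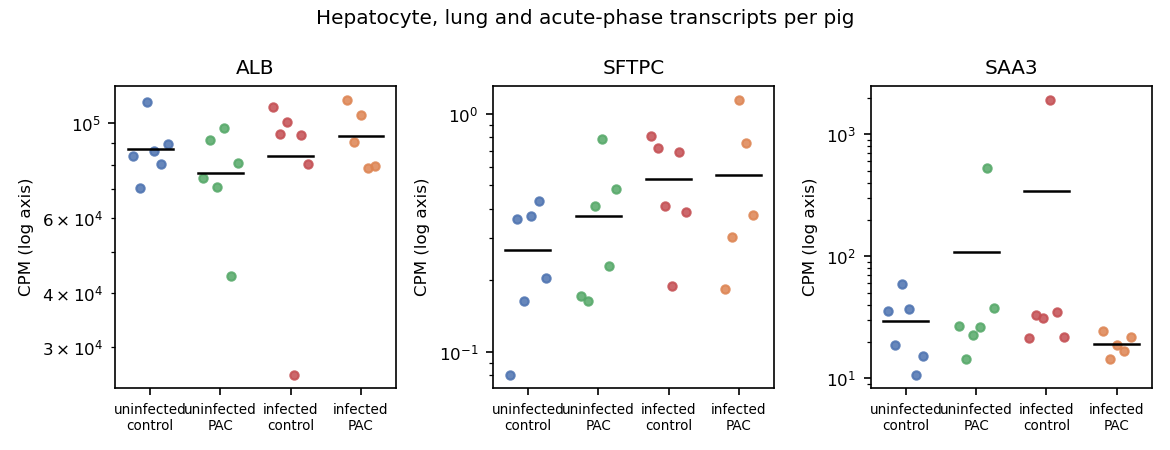
CPM of ALB, SFTPC and SAA3 in each of the 23 libraries, by group, on log axes; each point is a pig and the black line is the group mean. ALB lies between 25820 and 113474 CPM and SFTPC between 0.0803 and 1.15 CPM in every library, and SAA3 is high in infected control-diet replicate 4 (1924 CPM) and uninfected PAC-diet replicate 5 (529 CPM).

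Infection, averaged over the diets (11 infected against 12 uninfected pigs), went with higher PCK1, IGFBP1 and G6PC, and with lower ALAS1, HSPA5 and FICD. In this and the other infection comparisons, an effect of infection cannot be told apart from a difference in sampling hour or feeding state. PCK1 (gene number 100144531), which encodes the cytosolic enzyme that commits carbon to gluconeogenesis, rose by 5.00 (SE 0.74), from 32.02 ± 31.3 to 1018 ± 935 CPM. IGFBP1 (397270), a secreted binder of insulin-like growth factors, rose by 4.88 (SE 0.66), from 11.3 ± 16.05 to 213 ± 156 CPM. G6PC, the phosphatase that frees glucose, rose by 2.75 (SE 0.46), and TAT, which starts tyrosine breakdown, rose by 1.85 (SE 0.20). ALAS1 (100307125), the rate-limiting enzyme of haem synthesis, fell by 2.51 (SE 0.24), from 1203 ± 435 to 207 ± 97.5 CPM. In all, 4383 genes changed, 2050 up and 2333 down, and 405 of them changed by more than 2-fold. Other genes with large changes were ULK1, a kinase that starts autophagy (2.73, SE 0.31), RNF125, a ubiquitin ligase (2.81, SE 0.28), SOCS2, a feedback inhibitor of growth hormone signalling (2.52, SE 0.48), and HMCN2 (2.12, SE 0.35), all up, and TSKU, a secreted protein (−2.89, SE 0.37), ZFAND2A (−2.32, SE 0.20), MEI1 (−2.37, SE 0.24), NOCT (−1.83, SE 0.35) and PFKFB3, a regulator of glycolysis (−2.19, SE 0.45), all down. CYP2J34, a cytochrome P450 gene with close relatives that can share reads, fell by 2.75 (SE 0.90, adjusted p 0.0277), and its adjusted p was 0.0504 without uninfected control-diet replicate 6, 0.121 without uninfected PAC-diet replicate 3, 0.0628 with the replicate number as a block and 0.579 with limma voom with library weights. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 3.32e-05 for PCK1, 1.42e-05 for IGFBP1, 8.88e-08 for ALAS1 and 0.000875 for PFKFB3.

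Among metabolic lists, gluconeogenesis and glycogen had 7 of 20 tested genes up, 1 down and 12 that did not pass. Its members included PYGL, glycogen phosphorylase (0.43, SE 0.09), and FOXO1, a fasting-induced transcription factor (0.47, SE 0.08). Adjusted over the list alone the counts were 7 up and 2 down. By camera, which sets a list against all other genes, its adjusted p over 42 lists was 0.43, while fry, which asks if the list's own genes moved on balance to the same side, gave an adjusted p of 0.00198 (up). Fatty acid and triglyceride synthesis had 6 of 20 up and 0 down (6 and 0 adjusted over the list alone), among them LPIN1 (1.57, SE 0.17) and GPAM (1.05, SE 0.17), which act in triglyceride assembly, and THRSP (0.71, SE 0.18). The list's median was −0.04 although its mean was 0.16, and its camera adjusted p was 0.46. Fatty acid oxidation had 6 of 27 up and 2 down (also adjusted over the list alone, camera adjusted p 0.46), with PPARGC1A, a coactivator of fasting metabolism, at 0.63 (SE 0.10) and ANGPTL4 at −0.71 (SE 0.14). Bile acid genes had 3 of 19 up: ABCG8 (0.74, SE 0.12) and ABCG5 (0.39, SE 0.12), which export sterols into bile, and NR1H4, the bile acid receptor (0.44, SE 0.08), with a camera adjusted p of 0.694. Iron handling had 2 of 19 up, SLC40A1, the iron exporter ferroportin (0.81, SE 0.11), and STEAP3 (0.29, SE 0.09), and 1 down, SLC11A2 (−0.35, SE 0.08), with a camera adjusted p of 0.438 and a fry adjusted p of 0.0193 (up). TDO2, which opens the kynurenine path of tryptophan breakdown, rose by 0.72 (SE 0.11), from 502 ± 79.2 to 827 ± 167 CPM. Of 24 xenobiotic enzymes and receptors, FMO5 fell by 0.74 (SE 0.10) and the receptor NR1I2 by 0.41 (SE 0.07), the receptor NR1I3 rose by 0.41 (SE 0.09) and 21 did not pass, with a camera adjusted p of 0.961.

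**Figure D2:**
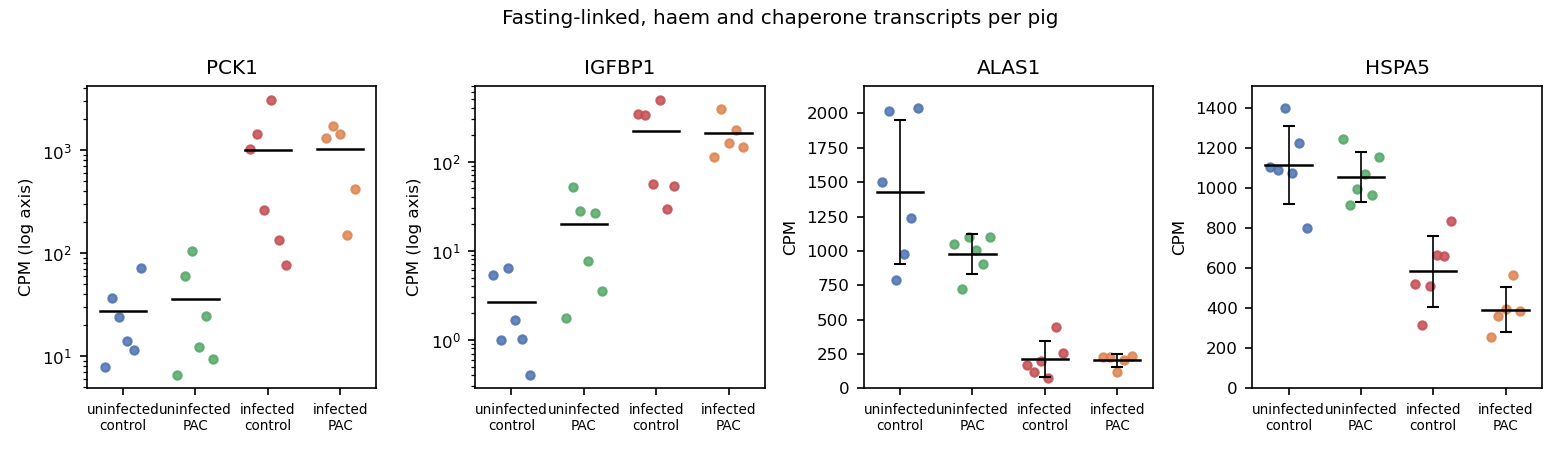
CPM of PCK1 and IGFBP1 (log axes) and of ALAS1 and HSPA5 (linear axes) in each pig, by group; points are pigs, and the black marks give the group mean, with SD bars on the linear axes. PCK1 and IGFBP1 were higher and ALAS1 and HSPA5 lower in the infected groups on both diets.

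Genes of the circadian clock changed in both directions with infection. ARNTL (100037286), an activator at the core of the clock, rose by 2.34 (SE 0.22), from 5.96 ± 4.54 to 25.3 ± 2.81 CPM, and its partner NPAS2 rose by 0.79 (SE 0.13). Genes that the activators switch on were lower: PER3 fell by 1.60 (SE 0.16), from 43.1 ± 13.7 to 14.0 ± 3.00 CPM, NR1D2 by 1.23 (SE 0.11), NR1D1 by 1.11 (SE 0.22), DBP by 0.92 (SE 0.17) and USP2 by 1.39 (SE 0.17). CRY1 rose by 0.76 (SE 0.12). Of 19 tested clock genes, 6 rose, 8 fell and 5 did not pass (7 up and 8 down adjusted over the list alone). By fry's test for change in either direction, which 20 of 42 lists passed, the list's adjusted p was 2.12e-12. By camera, which tests a shared direction, it was 0.617. The adjusted p was 7e-08 for ARNTL and 8.42e-08 for PER3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The hour at which each pig was killed and its last meal are not given in the sources used here.

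**Figure D3:**
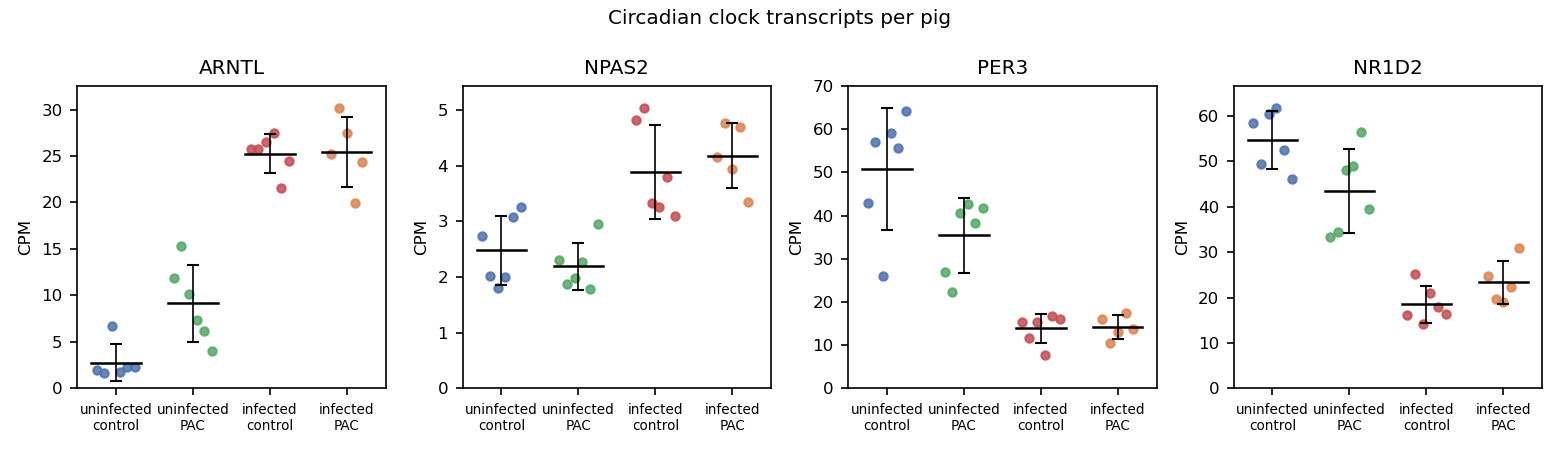
CPM of ARNTL, NPAS2, PER3 and NR1D2 in each pig, by group; points are pigs, and the black marks give mean ± SD. ARNTL averages 2.77 CPM in uninfected control-diet pigs, 9.16 CPM in uninfected PAC-diet pigs, 25.3 CPM in infected control-diet pigs and 25.4 CPM in infected PAC-diet pigs, and PER3 runs the other way.

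The endoplasmic reticulum stress list was lower on balance with infection by camera (adjusted p 0.00308), but not with its correlation estimated (adjusted p = 0.976 with an estimated correlation). Of 20 tested members, 10 fell, 3 rose and 7 did not pass (10 down and 4 up adjusted over the list alone). HSPA5 (407060), the main chaperone of the endoplasmic reticulum, fell by 1.18 (SE 0.14), from 1085 ± 160 to 497 ± 175 CPM, DNAJB9, its cofactor, by 1.59 (SE 0.12), and HYOU1, another chaperone there, by 1.54 (SE 0.17). HERPUD1 fell by 0.79 (SE 0.08) and MANF by 1.45 (SE 0.19), while SEL1L, a part of the protein disposal machinery, rose by 0.30. FICD (100621588), which modifies HSPA5 and was not on the list, fell by 2.80 (SE 0.18), from 34.2 ± 10.6 to 4.92 ± 1.31 CPM. The cytosolic chaperone genes HSPH1 and HSPA8 fell by 1.62 (SE 0.16) and 1.39 (SE 0.15), within an immediate early and heat shock list of 21 genes of which 3 rose, 5 fell and 13 did not pass. That list's median was 0.22 while its mean was −0.05, and its camera adjusted p was 0.558. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 3.27e-10 for FICD and 6.77e-07 for HSPA5.

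Immune genes that changed with infection included CCR3, IL33 and MRC1, while most immune lists did not pass as groups. In the type 2 cytokine signalling list, which holds the cytokines, receptors and regulators of that response, 6 of 16 tested genes rose and 1 fell (9 and 1 adjusted over the list alone). Among those that rose, CCR4 lost its call in 6 of 19 fits without 1 library (adjusted p up to 0.0677) and with no filter (0.0516). STAT6 lost it in 3 of 23 such fits (adjusted p up to 0.0691) and without both acute-phase pigs (0.0687). CCR3, the eotaxin receptor of eosinophils, rose by 1.92 (SE 0.32), from 0.285 ± 0.118 to 1.12 ± 0.625 CPM. IL33, an alarm cytokine of tissue cells, rose by 0.56 (SE 0.09), from 23.7 ± 1.93 to 34.8 ± 7.17 CPM, IL17RB by 0.45 (SE 0.13), and SOCS1, an inhibitor of cytokine signalling, fell by 0.58 (SE 0.16). The list's camera adjusted p was 0.128, and its fry adjusted p for shared direction was 0.00198 (up). Of 11 genes of alternatively activated macrophages 2 rose and 2 fell. The mannose receptor MRC1 (0.42, SE 0.08) and TGM2 (0.39, SE 0.11) rose, and CLEC10A (−0.88, SE 0.12) and CD200R1 (−0.84, SE 0.22) fell, with a camera adjusted p of 0.961. Of 18 macrophage and Kupffer cell genes 0 rose, 1 fell and 17 did not pass (camera adjusted p 0.961). Of 4 tested eosinophil genes CCR3 alone passed, too few for a list test. Mast cell genes had 3 of 5 up (camera adjusted p 0.43), MS4A2, KIT and FCER1A. MS4A2, a chain of the IgE receptor, rose by 0.44 (SE 0.14, adjusted p 0.0225), and its adjusted p was 0.0617 without infected PAC-diet replicate 3, while KIT lost its call without 9 of the 23 libraries and FCER1A without 14, at adjusted p up to 0.0753 and 0.0955. KIT also lost it with voom with library weights (0.0513), the replicate block (0.0572) and without both acute-phase pigs (0.0606), and FCER1A with no filter (0.0651) and with EIF1AY as a covariate (0.0509). None of the tested genes of T cells (16), cytotoxic lymphocytes (18), B cells (16) or neutrophils (9) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The values were −0.03 (SE 0.13) for CD3E of T cells and 0.14 for MS4A1 of B cells, with adjusted p of 0.899 and 0.613. CCL17, CCL24, CCL26, EPX and S100A8 were too low to test, as was GPX2. SAA3 (0.52, adjusted p 0.698) and HP (0.07) did not pass, nor did IL13RA2 (0.35), IL4R (−0.22) and HMOX1 (0.19). Without uninfected control-diet replicate 3, IL13RA2 (0.51, adjusted p 0.00729), IL4R (−0.30, adjusted p 0.0169) and HMOX1 (0.25, adjusted p 0.0414) passed. They also passed with voom with library weights and all libraries kept (0.004, 0.0194 and 0.0182 in the same order). Of the 32 genes of the fixed panel, 26 were tested, 3 rose (IL33, MRC1 and GCLC), 1 fell (TXNRD1) and 22 did not pass.

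The extracellular matrix and fibrosis list was higher on balance with infection by camera (adjusted p 0.00308), but not with its correlation estimated (adjusted p = 0.976 with an estimated correlation). Of 30 tested, 6 rose, 0 fell and 24 did not pass, also when adjusted over the list alone, and 28 had a positive log2 fold change. LOX, which cross-links collagen, rose by 0.61 (SE 0.19), FAP, a protease of activated fibroblasts, by 0.40 (SE 0.11), PDGFRB, a receptor of pericytes and stellate cells, by 0.35 (SE 0.10), and the fibrillar collagen gene COL5A2 by 0.27 (SE 0.08). COL1A1 (0.35, SE 0.20) and COL3A1 (0.23) did not pass, with adjusted p of 0.198 and 0.124, and both passed without uninfected control-diet replicate 1 (0.53, adjusted p 0.0119, and 0.28, adjusted p 0.0442). Endothelial markers had 4 of 15 up and 0 down (2 and 0 adjusted over the list alone), with KDR, a growth factor receptor of vessels, at 0.53 (SE 0.10) and EMCN at 0.39 (SE 0.11). Their camera adjusted p was 0.109 and their fry adjusted p 0.0193 (up). Of 5 tested erythroid genes 2 rose, HBB, a globin (1.081, SE 0.37), and AHSP, a globin chaperone (1.16, SE 0.35), with a camera adjusted p of 0.46. HBB had an adjusted p of 0.0341, which was 0.0511 to 0.0777 without uninfected control-diet replicate 1, uninfected PAC-diet replicate 1, 3, 4, 5 or 6, infected control-diet replicate 1 or infected PAC-diet replicate 1 or 5, 0.0596 with no filter, 0.0663 with the replicate block and 0.0668 without both acute-phase pigs. Hepatocyte markers had 2 of 30 up, TAT among them, and ALB was at 0.12 with an adjusted p of 0.663.

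Antioxidant genes controlled by NRF2 did not share a direction. GCLC (100522018), the rate-limiting enzyme of glutathione synthesis, rose by 1.03 (SE 0.10), from 105 ± 22.3 to 214 ± 22.2 CPM, and SQSTM1 rose by 0.38 (SE 0.08), while SRXN1 fell by 0.81 (SE 0.15) and TXNRD1, thioredoxin reductase, by 0.42 (SE 0.09). Of 28 tested, 2 rose and 4 fell (2 and 3 adjusted over the list alone). NQO1 (0.09) did not pass, with an adjusted p of 0.667, nor did CYP1A1 (−0.49, adjusted p 0.116), which passed without infected control-diet replicate 6 (−0.62, adjusted p 0.0366). The list's camera adjusted p was 0.966, and its fry adjusted p for change in either direction was 2.12e-12. With 4383 of 15955 genes changed, 20 of 42 lists passed that fry test, so passing it is not particular to antioxidant genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, GCLC had an adjusted p of 4.43e-08.

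On the control diet, infection (6 against 6 pigs) went with a rise in IGFBP1 of 6.38 (SE 1.01), from 2.63 ± 2.55 to 218 ± 197 CPM. PCK1 rose by 5.19 (SE 1.04), from 27.7 ± 24.2 to 1015 ± 1167 CPM. ARNTL rose by 3.21 (SE 0.32), from 2.77 ± 1.97 to 25.3 ± 2.06 CPM, and ULK1 by 3.10 (SE 0.44), from 26.9 ± 10.0 to 230 ± 96.0 CPM. FICD fell by 2.82 (SE 0.24), from 38.2 ± 7.98 to 5.38 ± 1.65 CPM, and ALAS1 by 2.76 (SE 0.33), from 1425 ± 525 to 211 ± 130 CPM. TSKU (−3.06, SE 0.50), NOCT (−2.77, SE 0.48), MEI1 (−2.69, SE 0.33) and MFSD2A, a lipid transporter (−2.37, SE 0.48), and ZFAND2A (−2.38, SE 0.27) also fell, and RNF125 (2.91, SE 0.40) and ELF3 (3.01, SE 0.66) rose. SOCS2 (2.63, SE 0.66), IP6K3 (2.45, SE 0.69) and CYP2J34 (−4.58, SE 1.30) passed as well, but not with limma voom with library weights (adjusted p 0.288, 0.095 and 0.364), and SOCS2 also not with only the groups compared (0.0664) or the replicate block (0.0581). In total 2651 genes changed, 1165 up and 1486 down. The clock list had 6 of 19 up and 8 down (6 and 9 adjusted over the list alone), with PER3 at −1.87 (SE 0.21) and CRY1 at 1.07 (SE 0.16). Of 20 endoplasmic reticulum stress genes 6 fell and 1 rose (9 and 2 adjusted over the list alone), with HSPA5 at −0.93 (SE 0.19), and the camera adjusted p was 0.107. IL33 rose by 0.50 (SE 0.12) and GCLC by 1.21 (SE 0.14), from 94.98 ± 23.5 to 219 ± 14.6 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.000189 for IGFBP1, 0.00165 for PCK1, 1.2e-06 for ARNTL, 7e-06 for ALAS1 and 0.00609 for IL33.

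Extracellular matrix genes on the control diet had 27 of 30 log2 fold changes above 0, and 2 passed the gene test, FAP (0.46, SE 0.15, adjusted p 0.0377) and MMP2 (0.51, SE 0.17, adjusted p 0.039), with 0 adjusted over the list alone. The adjusted p of FAP was 0.0532 to 0.0795 without infected control-diet replicate 1, 2, 3, 4 or 6 or uninfected control-diet replicate 2, 3, 4 or 5. That of MMP2, a matrix protease, was 0.0518 to 0.109 without infected control-diet replicate 2 or 3 or uninfected control-diet replicate 2, 3, 5 or 6. Both also lost the call with voom with library weights (0.122 and 0.0708), the replicate block (0.0625 and 0.0505) and without both acute-phase pigs (0.0849 and 0.0544), FAP with no filter (0.0567) and MMP2 with only the groups compared (0.0864). The camera adjusted p of the list was 0.0202, and adjusted p = 0.974 with an estimated correlation. It was 0.0717, 0.155 and 0.138 without uninfected control-diet replicates 2, 3 and 5, and 0.0962 without infected control-diet replicate 2. By fry's test for shared direction 0 lists passed for infection on this diet. ARG1, an arginase of hepatocytes and of alternatively activated macrophages, fell by 0.61 (SE 0.20), from 288 ± 72.7 to 188 ± 38.9 CPM. Its adjusted p was 0.0413 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and lay between 0.0503 and 0.115 without any of uninfected or infected control-diet replicates 3, 4, 5 and 6. It was 0.0526 with no filter, 0.0673 with voom with library weights, 0.0671 with the replicate block and 0.0754 without both acute-phase pigs. SAA3 had a log2 fold change of 3.55 (SE 1.25) that did not pass (adjusted p 0.0586). It rested on infected control-diet replicate 4, without which the log2 fold change was −0.04, and it passed without infected control-diet replicate 1, 3, 5 or 6, with adjusted p from 0.0439 to 0.0499. Of the 26 panel genes tested, 2 rose (IL33 and GCLC), 1 fell (ARG1) and 23 did not pass. IL4R (adjusted p 0.00812), TXNRD1 (0.00921) and CXCL10 (0.0388) passed without uninfected control-diet replicate 3, TXNRD1 (0.02) without infected control-diet replicate 6, and COL1A1 (0.0173) without uninfected control-diet replicate 1. With all libraries kept, TXNRD1 passed with DESeq2 (0.0403), voom with library weights (0.00615) and the replicate block (0.0464). IL4R (0.00847) and IL13RA2 (0.0325) passed with voom.

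On the PAC diet, infection (5 against 6 pigs) went with a rise in PCK1 of 4.81 (SE 1.04), from 36.3 ± 39.0 to 1022 ± 694 CPM. G6PC rose by 3.34 (SE 0.67), from 40.9 ± 16.9 to 414 ± 253 CPM. IGFBP1 rose by 3.37 (SE 0.87), from 19.96 ± 19.5 to 207 ± 110 CPM. PFKFB3 fell by 3.10 (SE 0.68), FICD by 2.78 (SE 0.26), and ALAS1 by 2.27 (SE 0.35), from 980 ± 146 to 203 ± 49.7 CPM. LGR5, a receptor of Wnt-responsive hepatocytes around the central vein, fell by 2.04 (SE 0.28), from 12.8 ± 2.53 to 3.12 ± 0.606 CPM. RETREG1, a receptor for autophagy of the endoplasmic reticulum, rose by 2.53 (SE 0.29), MYBPC3, a sarcomere protein, by 3.05 (SE 0.55), HMCN2 by 2.80 (SE 0.51) and RNF125 by 2.72 (SE 0.40), while TSKU fell by 2.72 (SE 0.53), ZFAND2A by 2.27 (SE 0.29) and MEI1 by 2.05 (SE 0.34). SOCS2 rose by 2.42 (SE 0.68, adjusted p 0.0205), with an adjusted p of 0.0504 without infected PAC-diet replicate 5. In total 2321 genes changed, 1044 up and 1277 down. Of 20 endoplasmic reticulum stress genes 9 fell and 1 rose (10 and 2 adjusted over the list alone), with HYOU1 at −2.02 (SE 0.25) and HSPA5 at −1.43 (SE 0.20). Their camera adjusted p was 0.00012, and adjusted p = 0.736 with an estimated correlation. The clock list had 4 of 19 up and 3 down (6 and 3 adjusted over the list alone), with ARNTL at 1.47 (SE 0.30) and PER3 at −1.33 (SE 0.22). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.00337 for PCK1, 0.0121 for IGFBP1, 7.02e-06 for RETREG1 and 1.41e-05 for HYOU1.

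KDR and EMCN of vessels, the mannose receptor gene MRC1 and the cytokine gene IL33 were also higher in infected pigs on the PAC diet. KDR rose by 0.57 (SE 0.14), from 91.7 ± 9.47 to 136 ± 13.6 CPM, EMCN by 0.65 (SE 0.16), MRC1 by 0.68 (SE 0.12), from 103 ± 13.1 to 166 ± 20.4 CPM, and IL33 by 0.61 (SE 0.13). Of 18 macrophage and Kupffer cell genes 0 passed (camera adjusted p 0.87), and of 11 of alternatively activated macrophages 1 rose and 1 fell (0.919). The endothelium list had 2 of 15 up and 0 down (3 and 0 adjusted over the list alone), with a camera adjusted p of 0.0185, and adjusted p = 0.736 with an estimated correlation. Without uninfected PAC-diet replicate 5 it was 0.0615, and without both acute-phase pigs 0.0573. No extracellular matrix gene passed among 30 on this diet (0 adjusted over the list alone), and the list's camera adjusted p was 0.0185, and adjusted p = 0.941 with an estimated correlation. It was 0.0747 without uninfected PAC-diet replicate 5, and 0.0677 and 0.222 without infected PAC-diet replicates 1 and 4, and 0.0714 without both acute-phase pigs. NQO1 rose by 0.60 (SE 0.19), from 12.3 ± 2.14 to 18.6 ± 2.85 CPM, and CYP1A1, a target of the aryl hydrocarbon receptor, fell by 1.06 (SE 0.33), from 420 ± 123 to 201 ± 37.7 CPM. Their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0318 and 0.0345. That of NQO1 lay between 0.0569 and 0.101 without uninfected PAC-diet replicate 1, 3 or 5 or infected PAC-diet replicate 2, 4 or 5, and that of CYP1A1 between 0.067 and 0.088 without uninfected PAC-diet replicate 1 or 4 or infected PAC-diet replicate 1, 2, 3 or 5. With the replicate block they were 0.0767 and 0.0683, and that of CYP1A1 was 0.0658 with no filter. Of the 26 panel genes tested, 4 rose (IL33, MRC1, GCLC and NQO1), 2 fell (TXNRD1 and CYP1A1) and 20 did not pass, of which HMOX1 passed without infected PAC-diet replicate 4 (adjusted p 0.0364). HMOX1 also passed with the stricter filter (0.0492), only the groups compared (0.0323), voom with library weights (0.00613) and without both acute-phase pigs (0.0386).

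The response to infection was compared between the diets to ask if PAC altered it. Of the genes called on each diet, 521 rose on both and 803 fell on both, where independent sets would share 76.2 and 119, and 4 went opposite ways, where 190 would be shared. The log2 fold changes correlated across 15955 genes with Pearson's r of 0.520 and Spearman's rho of 0.537, and 70.0% had the same sign; genes are not independent replicates. Of the 2651 genes called on the control diet, 94.9% had the same sign on the PAC diet. The interaction, which tests if the fold changes differ, passed for 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 1282 genes at an unadjusted p under 0.05. DESeq2 called 30 and limma voom with library weights 26. The genes nearest to passing were UPP2, a uridine phosphorylase (1.18, SE 0.20, adjusted p 0.054), DHRS3, a retinaldehyde reductase (1.16, SE 0.21, adjusted p 0.0699), ZNF318 (−0.85, SE 0.16, adjusted p 0.0803), ZSCAN31 (1.39, SE 0.29) and TAOK1 (−0.64, SE 0.13), the last pair with an adjusted p of 0.187. ARNTL had an interaction of −1.74 (SE 0.43, adjusted p 0.268). The interaction count was 14 without uninfected control-diet replicate 3, with ARNTL at −2.21 (adjusted p 0.016) and UPP2 (adjusted p 0.0225), 8 without infected PAC-diet replicate 4, 4 without uninfected control-diet replicate 4 and 3 without infected control-diet replicate 4. UPP2 passed without uninfected control-diet replicate 3, 4 or 5, uninfected PAC-diet replicate 4, infected control-diet replicate 4 or infected PAC-diet replicate 4 or 5 (adjusted p 0.0104 to 0.0485). DHRS3 passed without uninfected control-diet replicate 1, 3 or 4, infected control-diet replicate 2 or infected PAC-diet replicate 4, and ZNF318 without uninfected control-diet replicate 3 or 4, infected control-diet replicate 1 or infected PAC-diet replicate 4 (both 0.0265 to 0.0462). ZSCAN31 passed without uninfected control-diet replicate 3 (0.0372) and TAOK1 without replicate 4 of that group (0.0462). With all libraries kept, UPP2 passed with no filter (0.0357), the stricter filter (0.0489) and EIF1AY as a covariate (0.0335). DHRS3 passed with the replicate block (0.0272) and EIF1AY (0.0348). Both, and ZNF318, ZSCAN31, TAOK1 and ARNTL, passed with DESeq2 (0.000113 to 0.0263) and with voom with library weights (0.0138 to 0.036). The interaction count was 1 without uninfected control-diet replicate 1 or 5, uninfected PAC-diet replicate 4, infected control-diet replicate 1 or 2, or infected PAC-diet replicate 5.

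Fatty acid oxidation was the list with an interaction past the camera threshold: 20 of 27 genes had a more positive infection effect on PAC (adjusted p 0.0172, and adjusted p = 0.823 with an estimated correlation), and 0 passed as single genes, over all genes or adjusted over the list alone. ANGPTL4 (1.00, adjusted p 0.326) and CPT2, which imports acyl groups into mitochondria (0.84, adjusted p 0.595), were examples by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list's adjusted p was 0.0619 without uninfected control-diet replicate 2, and 0.0637 and 0.0929 without infected PAC-diet replicates 1 and 2. By fry's test for shared direction 0 lists passed for the interaction. The clock list, with 0 genes past the test over all genes and 2 up and 1 down adjusted over the list alone, had an adjusted p of 0.00846 for change in either direction by fry.

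**Figure D4:**
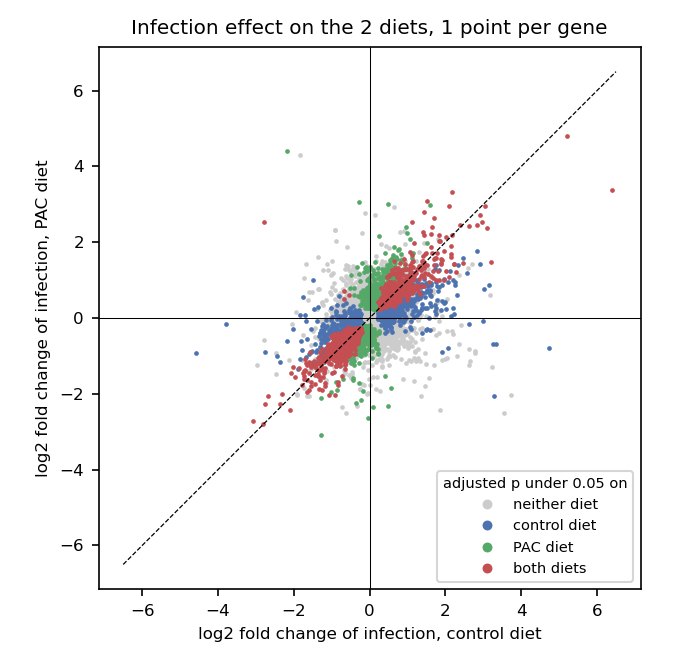
Log2 fold change with infection on the control diet (horizontal axis) against that on the PAC diet (vertical axis), a point per tested gene (15955 genes), coloured by the comparisons in which the adjusted p was under 0.05; the dashed line marks equal change. Of the genes called on both diets, 521 were up and 803 down on both, and 4 went opposite ways.

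In uninfected pigs, PAC (6 against 6 pigs) went with a change in 2 genes. ZNF318 (100153069), a zinc finger gene, rose by 0.65 (SE 0.11), from 17.4 ± 2.57 to 27.3 ± 2.64 CPM, and DHRS3 (100514967), which turns retinaldehyde into retinol, fell by 0.84 (SE 0.14), from 230 ± 47.6 to 129 ± 20.6 CPM. The adjusted p was 0.0414 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1556 genes had an unadjusted p under 0.05. ARNTL had a log2 fold change of 1.75 (SE 0.31, 2.77 ± 1.97 against 9.16 ± 4.12 CPM) with an adjusted p of 0.0593, and CRY1 (0.62, adjusted p 0.219) and DBP (−0.83, adjusted p 0.254) did not pass. Adjusted over the list alone, 4 of 19 clock genes were higher and 4 lower, against 0 over all genes, and the list's fry adjusted p for change in either direction was 0.000328. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was at 588 ± 120 against 281 ± 112 CPM, a log2 fold change of 1.07 that did not pass (adjusted p 0.437), and 0 of the 26 panel genes tested passed. Proliferation genes had 23 of 28 positive log2 fold changes, 0 past the test over all genes or adjusted over the list alone, and a camera adjusted p of 0.00631, and adjusted p = 0.917 with an estimated correlation. By fry's test for shared direction 0 lists passed in this comparison.

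The calls for PAC in uninfected pigs depended on single libraries. Both genes were lost, with adjusted p from 0.0659 to 0.187, without uninfected control-diet replicate 2, 5 or 6 or uninfected PAC-diet replicate 1, 2, 3, 4 or 5, each of which left 0 genes. Both were also lost with only the groups compared (0.184 each) and without both acute-phase pigs (0.161 for DHRS3 and 0.116 for ZNF318), and ZNF318 with the replicate block (0.0723). Without uninfected control-diet replicate 3 there were 38 genes, among them ARNTL (2.22, adjusted p 0.000197) and CRY1 (0.76, adjusted p 0.0371), and without uninfected PAC-diet replicate 6 there were 12, ARNTL included (adjusted p 0.0198). These values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 60 genes and limma voom with library weights 77, and ARNTL passed with both (adjusted p 3.72e-05 and 0.0069). ARNTL also passed with the stricter filter in edgeR (0.0382). CRY1 (0.0224), DBP (0.044) and NR1D1 (0.0487) passed with voom, and HLF with DESeq2 (0.0376). The camera adjusted p of the proliferation list was 0.0597, 0.109 and 0.151 without uninfected control-diet replicates 2, 4 and 5, and 0.0848 and 0.201 without uninfected PAC-diet replicates 2 and 3.

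In infected pigs, PAC (5 against 6 pigs) went with a rise in 3 genes and a fall in 0. RETREG1 (100625174) rose by 1.64 (SE 0.28), from 5.91 ± 1.65 to 18.4 ± 9.27 CPM. UPP2 (100522709), which breaks uridine down in the liver, rose by 0.84 (SE 0.14), from 98.6 ± 11.4 to 176 ± 41.8 CPM. MYBPC3 (100628050) rose by 3.33 (SE 0.57), from 0.519 ± 0.344 to 5.13 ± 5.03 CPM, with single pigs on PAC between 0.501 and 12.9 CPM. The adjusted p was 0.0334 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1043 genes had an unadjusted p under 0.05. Without any of the 6 infected control-diet libraries, or infected PAC-diet replicate 2 or 3, 0 genes were left, and 1 was left without infected PAC-diet replicate 1. The adjusted p of these genes where they were lost ran from 0.0521 to 0.188, which for RETREG1 also held without infected PAC-diet replicate 5 and for MYBPC3 without infected PAC-diet replicate 4. All 3 were also lost with only the groups compared (0.332 to 0.463), the replicate block (0.295 each) and without both acute-phase pigs (0.0623 to 0.0782), RETREG1 and MYBPC3 with no filter (0.0608 and 0.0706), and MYBPC3 with voom with library weights (0.22). ARNTL was at 0.01 (SE 0.29), and 0 of the 26 panel genes tested passed.

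Several lists were shifted by camera in infected pigs on PAC without a member past the test over all genes. By fry's test for shared direction 0 of 42 lists passed in this comparison. Proliferation genes had 26 of 28 positive values (adjusted p 0.000337, and adjusted p = 0.924 with an estimated correlation), 1 of them past the test adjusted over the list alone. TOP2A, a topoisomerase of dividing cells, was at 0.54. Goblet cell and mucus genes had 10 of 11 negative values (adjusted p 0.00532, and adjusted p = 0.827 with an estimated correlation), with MUC13 at −1.82, FCGBP at −0.62 and 1 lower adjusted over the list alone. Endoplasmic reticulum stress genes were lower on balance (adjusted p 0.0173, and adjusted p = 0.924 with an estimated correlation), with HYOU1 at −0.86 and HSPA5 at −0.57. Type 1 interferon response genes were lower, with 24 of 26 negative, MX1 at −0.53 and OAS2 at −0.56, and xenobiotic enzyme and fatty acid oxidation genes were higher, each list with an adjusted p of 0.0275. Interferon genes had adjusted p = 0.995 with an estimated correlation, and the other lists had adjusted p = 0.827 with an estimated correlation each. Clock genes were higher on balance (adjusted p 0.0372, and adjusted p = 0.827 with an estimated correlation).

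Single libraries decided several of these list calls. Without infected control-diet replicate 4, 1 of the acute-phase pigs, the camera adjusted p was 0.421 for interferon, xenobiotic and clock genes, 0.133 for fatty acid oxidation and 0.0812 for endoplasmic reticulum stress. Without infected PAC-diet replicate 1 it was 0.201, 0.292, 0.285, 0.169 and 0.3 in the same order, and without infected PAC-diet replicate 2 it was 0.337, 0.0511, 0.0511 and 0.176 for the interferon, xenobiotic, clock and fatty acid oxidation lists. Without infected PAC-diet replicate 5 it was 0.199 for proliferation, 0.199 for interferon and 0.0538 for clock genes. Without infected control-diet replicate 2 it was 0.0547 for xenobiotic and 0.0545 for fatty acid oxidation genes, without replicate 3 of that group 0.367 for interferon and 0.0603 for fatty acid oxidation genes, and without replicate 6 of that group 0.305 for endoplasmic reticulum stress. Without uninfected control-diet replicate 3 it was 0.0641 for clock genes. The goblet cell and mucus list passed with each of the 23 libraries left out.

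**Figure D5:**
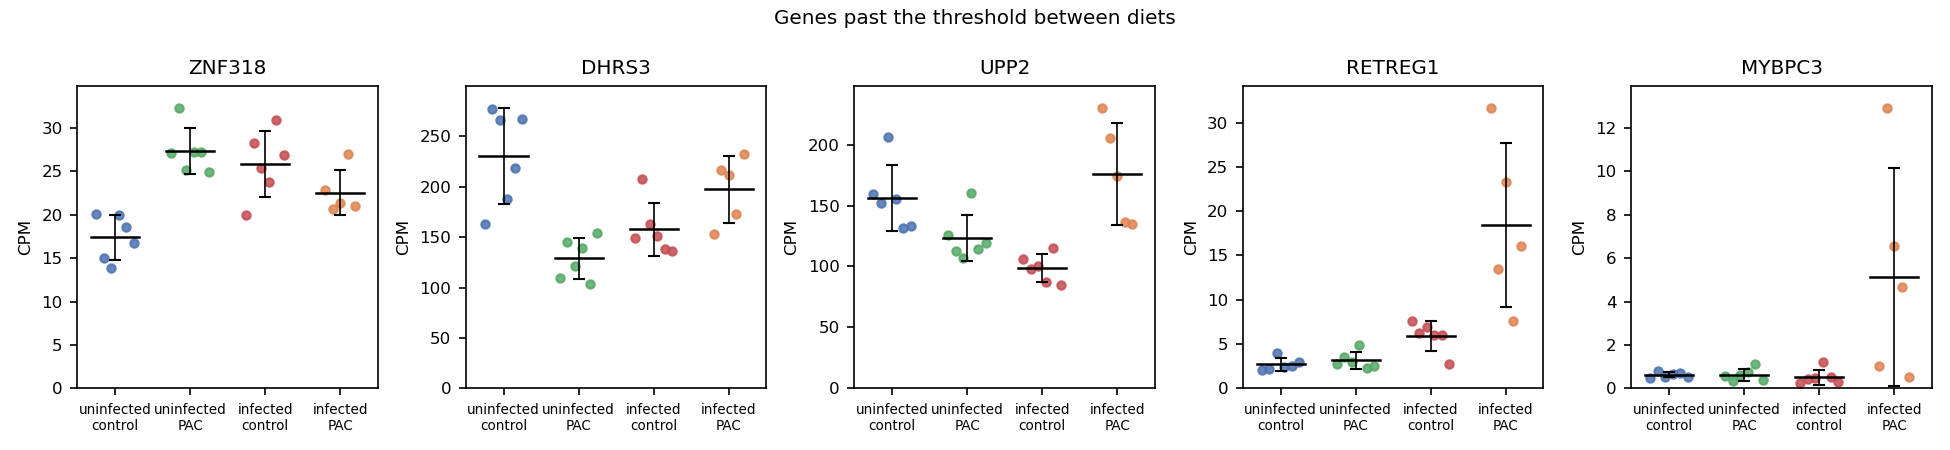
CPM of ZNF318, DHRS3, UPP2, RETREG1 and MYBPC3 in each pig, by group; points are pigs, and the black marks give mean ± SD. ZNF318 and DHRS3 differed between the diets in uninfected pigs, and UPP2, RETREG1 and MYBPC3 in infected pigs.

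Averaged over infection (11 pigs on PAC against 12 on the control diet), 0 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 1312 at an unadjusted p under 0.05, while DESeq2 called 38 and limma voom with library weights 29. Among the genes with the smallest p values were FOXO3, a stress-responsive transcription factor (0.46, SE 0.09, 153 ± 24.2 against 113 ± 22.1 CPM), CEP85 (0.38, SE 0.08), TRAF2 (−0.39, SE 0.08) and WDR74 (−0.39, SE 0.08), all with an adjusted p of 0.152. Proliferation genes were shifted upward, with 27 of 28 positive, a median of 0.31 and 6 higher adjusted over the list alone. BUB1 was at 0.65, CENPF at 0.67 and KIF11 at 0.42, which act at mitosis. The camera adjusted p was 4.54e-07, and adjusted p = 0.956 with an estimated correlation. By fry's test for shared direction 0 lists passed in this comparison. Goblet cell and mucus genes had 10 of 11 negative values (camera adjusted p 0.0205, and adjusted p = 0.956 with an estimated correlation), and the adjusted p was 0.0714 without infected PAC-diet replicate 5, 0.0769 with the replicate number as a block and 0.0924 with no filter. Gene counts were 9 without uninfected control-diet replicate 3, ARNTL included (1.11, adjusted p 0.00791), 2 without uninfected control-diet replicate 2 or infected control-diet replicate 4, and 1 without infected control-diet replicate 2. CEP85 passed without uninfected control-diet replicate 2 (adjusted p 0.0246). With all libraries kept, FOXO3, CEP85, TRAF2, WDR74 and ARNTL passed with DESeq2 (0.00532 to 0.0253) and with voom with library weights (0.0201 to 0.0433).

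Whether PAC in infected pigs moved genes against the direction of infection was asked by comparing both sets of fold changes, which share the infected control-diet pigs. Infection on the control diet and PAC in infected pigs had a covariance of −0.0325 across 15955 genes. The shared controls alone gave −0.0444 in 100 simulations of unchanged groups (from −0.0564 to −0.0343), a difference of 0.0119. The correlation was −0.218, against −0.474 simulated, and 48.4% of genes had the same sign, against 34.0%. The simulated groups held no infection effect. Real changes with infection weaken this correlation and this sign bias whatever PAC does, so the gaps in both say nothing about PAC. Genes were also drawn independently, so the simulated range of the covariance is too narrow. With the shared pigs split so that each comparison used its own, the covariance was 0.0154 over 20 splits (from −0.00794 to 0.0561) and r was 0.072.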

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

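The tests of a lower hepatocyte share and of swapped labels, and the EIF1AY counts of the splits, were chosen after their results were seen, and the list tests of the acute-phase pigs and of sampling hour were chosen after the pattern but before their own results.

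Clock and fasting-linked genes differed between infected and uninfected pigs, with ARNTL and PCK1 up and PER3 and ALAS1 down. A lower share of hepatocytes would raise markers of every other cell type alike. The infection effects of 11 lists of other cell types lay further apart than permuted labels give (permutation p = 0.0015, 10000 permutations within diets). The shift common to all lists was taken off, and a lower share would act through that shift. The test therefore shows that the lists did not move alike, but cannot tell whether the hepatocyte share also fell. The hepatocyte list itself stood at 0.0977 in infected against uninfected pigs (adjusted p 0.144 by permutation within diets). A difference in sampling hour or feeding state may underlie the pattern: if so, genes that follow the clock score among uninfected pigs would change with infection as well, and the correlation across genes was 0.0543 (one-sided permutation p = 0.333) with 12 uninfected pigs and 0.253 (p = 0.0281) with 11 infected pigs. The value among uninfected pigs was 0.000739 without the 2 pigs farthest from the median score, so it neither shows nor excludes a common hour, and the hour and an effect of infection cannot be told apart here. An effect of infection on metabolism stays open and untested.

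A pair of pigs, infected control-diet replicate 4 and uninfected PAC-diet replicate 5, carried high acute-phase transcripts. Swapped infection labels are argued against by ARNTL, at 27.5 CPM in the infected pig (19.9 to 30.1 in the other infected pigs) and 6.19 CPM in the uninfected pig (1.61 to 15.3 in the other uninfected pigs). T and B cell genes rose by 0.666 of the rise of the acute-phase list in uninfected PAC-diet replicate 5. In infected control-diet replicate 4 they rose by 0.201 of it. Leukocyte RNA as the source of the acute-phase transcripts would raise them at least as much as that list. The smaller rises argue against RNA of T and B cells as that source in both pigs. Other leukocytes were not covered by this test and stay open. Leukocyte RNA in the sample cannot be told apart from inflammation, which brings leukocytes too. No group of the design gives a biological explanation that could be tested.

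In infected control-diet replicate 4, far from the other 5 pigs of its group, stood SAA3 at 1924 CPM (others 21.4 to 35.3), ITIH4 at 11441 (1791 to 2001), CD163 at 395 (92.1 to 154), CXCL10 at 307 (19.5 to 37.5), IL33 at 49.4 (27.2 to 33.8), ALB at 25820 (80379 to 108984) and GCLC at 192 (217 to 232), and its hepatocyte list took 17.3% of counts (22.6% to 24.8%). In uninfected PAC-diet replicate 5, SAA3 stood at 529 CPM (14.5 to 38.0) and ITIH4 at 6122 (1356 to 1935). In uninfected control-diet replicate 3, MKI67 stood at 4.02 CPM (11.7 to 21.7), CXCL10 at 64.5 (12.9 to 20.2), TXNRD1 at 53.8 (73.7 to 84.2), CYP1A1 at 828 (301 to 408), HP at 20058 (9344 to 11587) and ARNTL at 6.74 (1.61 to 2.32), and its TMM library factor was 0.863 (1.00 to 1.06). MRC1 stood at 167 CPM in infected control-diet replicate 2 (123 to 135), ZNF318 at 32.3 CPM in uninfected PAC-diet replicate 2 (25.0 to 27.3) and RETREG1 at 2.78 CPM in infected control-diet replicate 6 (5.98 to 7.56). The mitochondrial share was 3.92% in uninfected PAC-diet replicate 6 (2.34% to 2.71%). Over 152 such tests 21 values stood apart, where chance gives about 1 in 20, or 7.6. Many of these values came from the same pigs, so they are not independent. Some genes outside the fixed panel, ITIH4 and ARNTL among them, were chosen after their values were seen. The 2 numbers are therefore a description and not a test. For the interaction, fatty acid oxidation genes had a camera adjusted p of 0.0172, and adjusted p = 0.823 with an estimated correlation. It was 0.0619 without uninfected control-diet replicate 2, 0.0637 and 0.0929 without infected PAC-diet replicates 1 and 2, and 0 of its 27 genes passed as single genes. Clock genes had a fry adjusted p of 0.00846 for an interaction in either direction.

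Gene counts were compared with 100 splits of the same libraries, the real split included, drawn at random. As many genes as in the real split were called in 1 split for infection on the control diet (2651 genes, at most 877 in other splits), in 1 for infection on PAC (2321, at most 1198) and in 1 for infection averaged over the diets (4383, at most 1), so chance can be excluded there. For PAC in uninfected pigs 4 splits gave as many (2 genes, at most 127) and for PAC in infected pigs 4 (3 genes, at most 17). With 100 random splits these shares are too near 0.05 to exclude chance, and each count was 0 without any of 8 single libraries. Splits with many times the real count point to a structure of the samples, whose source was not found. Libraries with EIF1AY counts were 4 and 2 in the arms of the split with 127 genes, and 2 and 4 in both splits with 17. For the interaction and for PAC averaged over infection the real count was 0, so 100 of 100 splits reached it (at most 1 and 3). For lists called by camera, chance could not be excluded in any comparison. As many as the real count came in 99 splits for infection on the control diet (1 list, at most 17), 95 on PAC (3, at most 16) and 98 averaged (2, at most 20), in 100 for PAC in uninfected pigs (1, at most 16), 77 in infected pigs (7, at most 20) and 97 averaged (2, at most 20), and in 98 for the interaction (1, at most 21).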

How the results depend on the processing

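The settings with EIF1AY, without both acute-phase libraries, and with infection on PAC set against PAC in uninfected pigs were chosen after the data were seen, and the others before. Of the values of single genes, 167 were called and 210 were not. Under at least 1 setting 30 of the called ones lost the call and 31 others gained one, and 0 reversed.

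The infection counts were within 1.5 times of 2651, 2321 and 4383 genes with RLE factors, DESeq2, no filter or the stricter filter. Exceptions were 1723 genes on the control diet with only the groups compared, 3708 on PAC with limma voom with library weights, and 1384, 1214 and 2778 at an adjusted p under 0.01, which follows from the threshold. Without both acute-phase libraries they were 2174, 2242 and 4074.

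The PAC and interaction counts moved with the settings named here, and apart from fewer libraries or the stricter threshold the cause was not tested. In uninfected pigs (2 genes), DESeq2 gave 60, voom with weights 77, only the groups compared 0, the fit without the acute-phase libraries 0 and an adjusted p under 0.01 0. In infected pigs (3 genes), no filter gave 1, DESeq2 8, voom with weights 11, only the groups compared 0, the fit without the acute-phase libraries 0 and an adjusted p under 0.01 0. The interaction (0 genes) gave 1 with no filter, 1 with the stricter filter, 30 with DESeq2, 26 with voom with weights and 2 with EIF1AY. PAC averaged over infection (0 genes) gave 38 with DESeq2 and 29 with voom with weights.

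Camera called 17 lists, 0 with an estimated correlation, 28 with no filter and 11 without the acute-phase libraries. The correlation of infection effects between diets, 0.520, was 0.862 over the 4383 genes called on average and 0.703 over genes with a mean of at least 10 CPM. The 4383 genes were chosen by the mean of the same effects, which by itself raises the correlation, and 99.3% of them had the same sign. The covariance of infection and PAC effects, −0.0325, was 0.0154 with the shared libraries split; for infection on PAC and PAC in uninfected pigs it was −0.0216, against −0.0440 simulated.

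With each library left out, infection gave 2053 to 2920 genes on the control diet, 1720 to 2438 on PAC and 3945 to 4886 averaged. PAC gave 0 to 38 genes in uninfected pigs, 0 to 3 in infected pigs and 0 to 9 averaged, and the interaction 0 to 14, each highest without uninfected control-diet replicate 3 except in infected pigs. Camera called 11 lists without infected PAC-diet replicate 1 and 31 without infected control-diet replicate 1, and the correlation between diets was 0.460 to 0.548.

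With the replicate number as a block, infection gave 2376, 1950 and 4018 genes, PAC 1 in uninfected, 0 in infected pigs and 0 averaged, and the interaction 1. The labels do not say that a number marks shared animals or batches, and not every pair had a correlation over 0.1, so the numbers were not taken as pairs: 33 pairs with the same number had correlations from −0.194 to 0.191, 10 of them over 0.1, and 12 correlated best with their own number, where chance gives 6 if the numbers carry nothing. EIF1AY was counted in replicates 1 and 3 of every group and in none of replicates 2 and 6, so the number went partly with it. In each of the 12 pairs EIF1AY was counted in both pigs or in neither. The excess is a hint from the data and not from the design, and a match in EIF1AY and a shared origin of the pigs cannot be told apart.

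At 16299240 to 29535440 counts per library the self-test found 37.2% to 45.1% of 1.5-fold changes, and 200 such changes gave 83 calls for PAC in uninfected and 78 in infected pigs, where the real counts were 2 and 3. The simulated genes were drawn independently, and no simulated pig stood apart across many genes as some real pigs did. The comparison therefore does not tell how many genes PAC changed.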

Other observations

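The added lists of ribosome biogenesis, secretory transport, haem synthesis and autophagy genes and the genes of the clock score were chosen after the leading infection genes were seen, with the genes already seen left out of the lists.

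Genes of ribosome biogenesis fell together with infection. Of 72 tested, 62 fell and 2 rose, with a median of −0.59 averaged over the diets, and on the single diets 53 fell and 2 rose (control) and 55 fell and 0 rose (PAC). RRP9 and PPAN, which act in processing the small and large ribosomal subunits, fell by 1.37 (SE 0.12) and 1.30 (SE 0.12), RPF2 by 1.21 (SE 0.13), and DDX18 and TSR1 by 1.06 (SE 0.10) and 1.06 (SE 0.11), while RCL1 rose by 0.35 (SE 0.12). The camera adjusted p over the 4 added lists was 7.97e-35, and adjusted p = 0.00602 with an estimated correlation.

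Transport genes of the secretory pathway had 20 of 51 down and 1 up, with SEC24D, a coat protein of vesicles leaving the endoplasmic reticulum, at −1.26 (SE 0.14), SRPRB at −1.07 (SE 0.14) and ARCN1 at −0.63 (SE 0.08). The camera adjusted p was 9.41e-05, and adjusted p = 0.336 with an estimated correlation, so a change of the class stays open. Autophagy core genes had 10 of 35 up and 7 down, with ATG2A (0.90, SE 0.13), ATG2B (0.82, SE 0.12) and ATG14 (0.77, SE 0.11) up and ATG4B (−0.39) and ATG101 (−0.37) down. Their camera adjusted p was 0.16, and adjusted p = 0.336 with an estimated correlation, while fry gave 0.00348 (up). Of 7 further haem synthesis genes 2 fell, UROD (−0.17) among them, and 5 did not pass, with a camera adjusted p of 0.288.

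A clock score, the mean log2 CPM of ARNTL, NPAS2 and CLOCK minus that of NR1D1, NR1D2, PER3, DBP and TEF, genes chosen after their values were seen, was −3.59 ± 0.356 in uninfected control-diet pigs (−4.12 to −3.20, n = 6) and −2.14 ± 0.554 in uninfected PAC-diet pigs (−2.84 to −1.41, n = 6), values that describe these pigs and test nothing. In infected pigs the score was −0.387 ± 0.310 (n = 6) on the control diet and −0.581 ± 0.362 (n = 5) on PAC.

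Mean log2 expression of cell type lists was compared between infected and uninfected pigs by a permutation test within diets (100000 permutations, two-sided, 12 lists). The endothelium list was higher by 0.189 (permutation p = 0.00127, adjusted p 0.0152). Erythroid genes (0.721), mast cell genes (0.324) and extracellular matrix genes (0.263) had an adjusted p of 0.0674 each, hepatocyte genes (0.0977) of 0.144, and T cell genes stood at 0.00363.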
